A study of Mus musculus with 12 samples.

How the data were processed

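The series holds 12 Illumina bead arrays of RAW264.7 cells, 3 per group, and each array is 1 biological replicate, per the labels. Per the labels' protocols, cells were given gefitinib at 10 µM for 1 h before CpG, and CpG at 10 µg/ml for 6 h, in DMEM with serum. The labels do not state how long cells without CpG were incubated. Signals were exported from GenomeStudio 2010.2, per the submitters' processing notes. The deposited signals are bead intensity values on a linear scale for 25697 probes per array, not normalized per the file headers, and they hold no value below 0. Each deposited signal comes with a detection p-value per the file headers, which ranks the probe among negative controls. The value table deposited by the authors holds the same intensity values after quantile normalization between the 12 arrays, on a linear scale and with no centring, as its shared quantiles and a Spearman correlation of 1 with the signals show. Its median was between 120.007 and 120.064 per array. Of the probes, 23978 had 1 gene symbol in the platform's annotation, 0 had several and 1719 were not listed there. Symbols were updated through the gene identifier for 23962 probes and through an accession for 9, and 7 were kept, which changed 8 symbols.

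From the signals, log2 values were computed with limma 3.58.1 in R 4.3.3 (neqc: normexp background correction from the detection p-values, offset 16, and quantile normalization). Probes with a detection p under 0.05 on at least 3 of the 12 arrays were kept (11977 probes, of which 11283 had a symbol), and the probe with the highest mean over the 12 arrays stood for its gene, which left 8101 genes. Of 2222 genes with several kept probes, 902 were called in CpG with gefitinib against CpG. Of these, 6 had a probe called the other way and 491 had a probe that was not called. In CpG against untreated the counts were 3 and 389 of 625, and in gefitinib against untreated 0 and 134 of 179. Sizes given for a gene are those of the chosen probe, and its other probes could give other sizes. In CpG with gefitinib against CpG, for example, the 2 probes of Oasl2 gave -4.83 and -1.35, and those of Il1rn -4.78 and -2.35. The 694 kept probes without a symbol were tested apart. Between 41.7% and 43.5% of the probes were detected per array.

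A linear model with the 4 groups was fitted to all 12 arrays (lmFit, eBayes, 8 residual and 5.07 prior degrees of freedom), with contrasts for CpG with gefitinib against CpG, CpG against untreated, gefitinib against untreated, CpG with gefitinib against gefitinib, and the interaction. The threshold was a Benjamini-Hochberg adjusted p of 0.05 over all genes. CpG-induced genes were those past it with a log2 change of at least 1. On data simulated from the fit, with 8101 genes of which 200 were changed and 20 runs, changes of 0.5, 1 and 2 log2 units were recovered in 39.5%, 97.1% and 100% of cases for CpG with gefitinib against CpG, in 41.2%, 97.6% and 100% for gefitinib against untreated, and in 40.0%, 96.7% and 100% for CpG with gefitinib against gefitinib, with 4.47%, 5.06% and 4.73% of calls false.

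A probe not detected on any array of a group has only a bound there. Its fold was taken from the mean of the brighter group against the mean, per array of the dimmer group, of the higher of its own value and the lowest value among detected probes. Medians of lists were computed with fitted values and again with such genes at their bounds.

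The 27 gene lists (874 members, 578 measured) were written before the data were examined, as were the groups, the comparisons, the rule for named genes and the alternatives. They were inflammatory cytokines, chemokines, NF-kB regulators and feedback genes, macrophage effector genes, interferon-stimulated genes, type I interferons, Toll-like receptor pathway components, ERK-dependent early and feedback genes, EGF receptor family with ligands and sheddases, cholesterol synthesis and uptake, fatty acid synthesis and LXR targets, lysosome and autophagy genes, ATF4 and amino acid response genes, unfolded protein response genes, NRF2 targets, DNA replication genes, mitosis genes, p53 targets, glycolysis and hypoxia genes, antigen presentation genes, macrophage identity genes, alternative activation genes, osteoclast genes, fibroblast and epithelial markers, lymphocyte and granulocyte markers, ribosomal protein genes, and mitochondrial respiratory chain genes. Each was tested with camera (preset correlation 0.01, adjusted over lists within a contrast), again with an estimated correlation, and with fry. Among called lists the sign of the median and of the test differed in 0 cases. With 26 lists shifted by 0.5 in turn in simulated data, camera called all 26, and 1 other list. The simulated noise was independent between genes. It therefore cannot show how the preset correlation performs for correlated lists, such as cholesterol synthesis and uptake with an estimated correlation of 0.344.

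For each comparison and the interaction, the named genes were the 10 with the largest positive and the 10 with the largest negative change among those past the threshold whose groups did not overlap, which chance gives for 10% of genes with 3 against 3 arrays (for the interaction, past the threshold alone). Predicted genes and clone names were passed over. Up to 4 members per list with the largest change and 12 genes fixed whatever their values (Tlr9, Egfr, Tnf, Il6, Il12b, Ifnb1, Cxcl10, Nos2, Ptgs2, Il1b, Ripk2 and Dusp6) were added.

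The alternatives were normexp on the signals alone (with the offset raised to 50), no background correction, cyclic loess, scaling to a common median, the value table of the authors, no filter on detection, detection p under 0.01 on all 12 arrays, the mean of a gene's probes, array weights, trend and robust eBayes, fits on the compared groups alone, the replicate number as a block, other thresholds, and leaving out each array. A block for the slide could not be fitted because the files give no slide, and list tests were not run with array weights. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 under Python 3.11.15.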

Results

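Messenger RNA was measured on 12 Illumina bead arrays in RAW264.7 cells, an established mouse macrophage line. The arrays formed 4 groups of 3 biological replicates, per the labels: untreated cells, cells given gefitinib, cells given CpG, and cells given CpG with gefitinib. CpG oligonucleotides mimic bacterial DNA and are sensed by the endosomal receptor TLR9, and gefitinib inhibits the tyrosine kinase of the EGF receptor. CpG was given at 10 µg/ml for 6 h, and gefitinib at 10 µM from 1 h before it. Of the 25697 probes, between 10705 and 11181 were detected on each array, and 8101 named genes were tested. The main axis of variation held 64.6% of the variance and parted the 3 arrays of CpG alone from the other 9. Arrays of gefitinib alone and of CpG with gefitinib differed by 0.257 log2 units on average (root mean square over genes), against 0.259 among the gefitinib arrays themselves and 0.619 between untreated and CpG arrays. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.14.

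Some genes had been fixed for description whatever their values. The 4 probes of Egfr, the receptor that gefitinib targets, were detected on 0 of the 12 arrays. Nos2, which encodes inducible nitric oxide synthase, was detected on 2 arrays, too few to be tested. Tlr9, Il12b and Ripk2 were not analysed here. Tnf and Dusp6 were detected on all 12 arrays, Cxcl10 on 5, and Il1b, Il6, Ifnb1 and Ptgs2 on 3, which were those of CpG alone.

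CpG alone switched on the inflammatory genes by which macrophages summon and arm other leukocytes, and lowered genes of DNA replication. Il1b, the gene of the fever-inducing cytokine interleukin-1 beta, was at least 167-fold higher with CpG than in untreated cells (limma, adjusted p = 1.05e-12), and Cxcl2, a neutrophil attractant, at least 87.2-fold (adjusted p = 7.73e-14). Tnf, the gene of tumour necrosis factor, rose by 4.17 ± 0.15 log2 units (± SE, n = 3 arrays per group, as in all that follows, adjusted p = 1.9e-10), from a mean of 8.62 to 12.79. Ifnb1, which encodes interferon beta, was at least 7.40-fold higher (adjusted p = 2.4e-10). "At least" marks genes whose probes were detected on no array of the dimmer group, so that their fold is a bound set by the lowest detected signal of each array. The adjusted p is then that of the fit. Named changes printed without an adjusted p passed the threshold, except where CpG with gefitinib is compared with gefitinib alone.

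In all, 2054 of the 8101 genes (25.4%) changed with CpG, 813 upward and 1241 downward, and at least 2-fold changes numbered 268 upward and 118 downward. The balance depended on the scaling, with 940 upward and 1019 downward under cyclic loess and 485 and 930 under median scaling. Ccl7, a monocyte attractant, was at least 63.9-fold higher (adjusted p = 2.36e-12) and Ccl2, detected on 1 of 3 untreated arrays, rose by 6.66 ± 0.23. Csf3, the granulocyte growth factor gene, was at least 37.8-fold higher by its brighter probe (adjusted p = 2.03e-12), while its other probe did not pass the threshold (0.00, adjusted p = 0.992). Phlda1 was at least 32.5-fold higher (adjusted p = 9.87e-12). Saa3, an acute-phase gene, rose by 5.56 ± 0.25, the interleukin-1 antagonist gene Il1rn by 4.93 ± 0.18, the NF-kB regulator Nfkbiz by 4.86 ± 0.15, and the niacin receptor gene Hcar2, detected on 2 of 3 untreated arrays, by 4.88 ± 0.25. Among the genes fixed in advance, Il6 was at least 6.68-fold higher (adjusted p = 6.58e-11) and Ptgs2, the cyclooxygenase-2 gene, at least 3.54-fold (adjusted p = 4.95e-05). Cxcl10, detected on 1 of 3 untreated arrays, rose by 4.37 ± 0.21 (adjusted p = 3.64e-09), and Dusp6, an ERK phosphatase gene, by 0.90 ± 0.12 (adjusted p = 8.18e-05). Cxcr4, the chemokine receptor gene, had the largest named decrease (-3.34 ± 0.20, adjusted p = 3.17e-08), with detection on 1 of 3 CpG arrays. St6gal1, a sialyltransferase gene, changed by -2.43 ± 0.15, Cytip by -2.31 ± 0.14, Agap1 by -2.08 ± 0.17, Fndc10 by -2.14 ± 0.13, Zdhhc14 by -1.77 ± 0.13, and Asb10, detected on 2 of 3 CpG arrays, by -2.42 ± 0.18. H2ac11, a histone H2A gene, changed by -1.82 ± 0.24, and Ranbp3l was at least 2.69-fold lower (adjusted p = 9.62e-07). Ypel3 fell by its brighter probe (-1.77 ± 0.19, adjusted p = 1.6e-05) and its other probe did not pass the threshold (-0.12, adjusted p = 0.728).

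**Figure D1:**
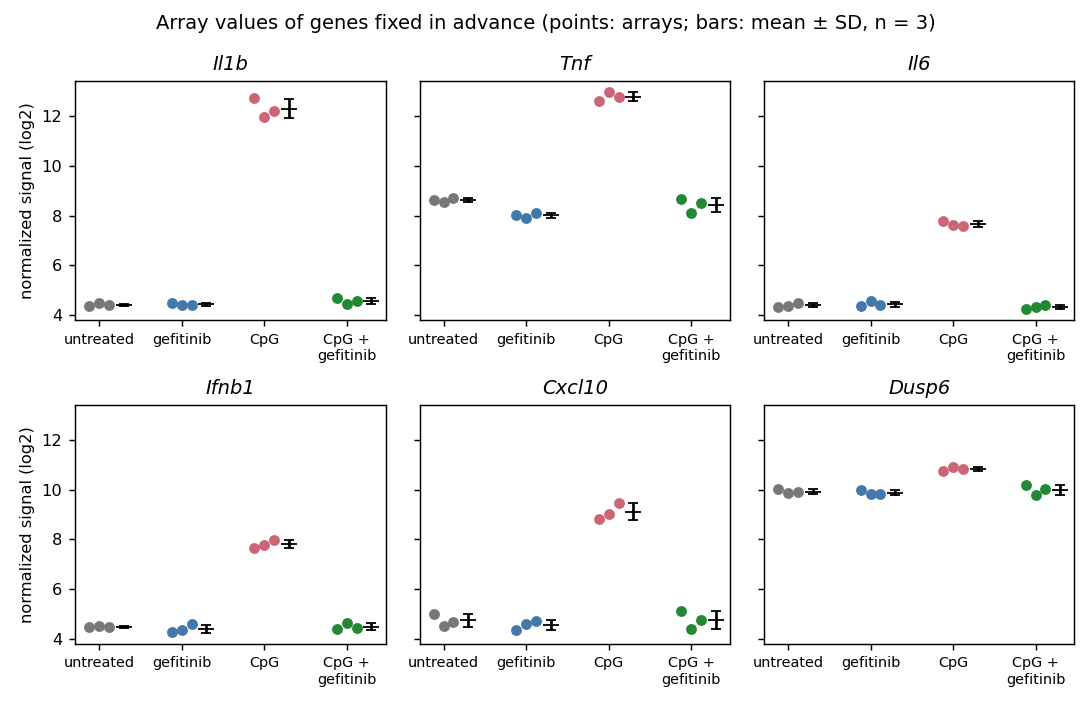
Normalized log2 signal of Il1b, Tnf, Il6, Ifnb1, Cxcl10 and Dusp6 on each array (points) with the mean and SD of each group (bars, n = 3). The 3 CpG arrays lie above the other 9 for each of these genes, and Tnf averaged 12.79 with CpG against 8.43 with CpG and gefitinib.

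Secreted mediators moved together as fixed lists, among the members measured. The detection filter let in genes detected on the 3 CpG arrays alone, while undetected members that CpG did not raise dropped out. Of 22 listed chemokines 10 were measured, and of 26 inflammatory cytokines 17, with 4 and 8 detected on no array of a compared group. Counts of members here and below therefore do not describe the whole lists. All 10 measured chemokine genes rose with CpG (10 adjusted over the list alone, median 4.32, camera adjusted p = 2.45e-22), among them Ccl3 (4.68 ± 0.16). Of 17 inflammatory cytokine genes, 15 rose and 1 fell (16 and 1 adjusted over the list alone), with a median of 2.45, or 2.05 with undetected members at their bounds (camera adjusted p = 1.28e-21), and Il1a was at least 19.5-fold higher. The exception was Il15, named after its value was seen, which fell by 0.82 ± 0.19, although 1 of its 3 probes did not pass the threshold. Interferon-stimulated genes followed, with 42 of 45 higher (43 adjusted over the list alone, median 1.77, or 1.74 with bounds, camera adjusted p = 1.48e-50), including Usp18 (4.58 ± 0.12) and Isg15 (4.27 ± 0.16). Of 4 measured type I interferon genes, Ifnb1 alone rose, and the list did not pass the set test (adjusted p = 0.0885). NF-kB regulators and feedback genes rose in 17 of 24 cases and 1 fell (the same adjusted over the list alone, median 1.33, or 1.28 with bounds, camera adjusted p = 2.9e-16). Socs3 changed by 4.69 ± 0.17 and Zc3h12a, an RNase gene, by 3.05 ± 0.18. Macrophage effector genes rose in 16 of 18 cases (17 adjusted over the list alone, median 1.62, or 1.44 with bounds, camera adjusted p = 3.77e-19), with Lcn2 at least 6.96-fold higher. ERK-dependent early and feedback genes rose in 14 of 25 cases and 1 fell (16 and 1 adjusted over the list alone, median 0.47, camera adjusted p = 3.26e-11). Ier3 changed by 3.17 ± 0.16 and Dusp2 by 2.38 ± 0.12. Of 6 EGF receptor family, ligand and sheddase genes, 3 rose (4 adjusted over the list alone, median 0.51, camera adjusted p = 0.00236), among them the receptor's feedback inhibitor Errfi1 (1.70 ± 0.11). Antigen presentation genes rose in 5 of 19 cases (7 adjusted over the list alone, median 0.22, camera adjusted p = 0.00108). Nlrc5 changed by 0.91 ± 0.17. Camera's calls for these lists, type I interferons aside, also held with an estimated correlation.

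Genes of DNA replication and mitosis were lower with CpG. DNA replication genes fell in 23 of 33 cases (27 adjusted over the list alone, median -0.54, camera adjusted p = 7.87e-10), including Clspn (-1.05 ± 0.10) and the transcription factor gene E2f2 (-1.29 ± 0.27). Mitosis genes fell in 11 of 25 (15 adjusted over the list alone, median -0.41, or -0.40 with bounds, camera adjusted p = 0.000207), including the spindle motor gene Kif11 (-0.66 ± 0.13). Both calls held with an estimated correlation. Fatty acid synthesis and LXR target genes fell in 8 of 16 cases and 1 rose (the same adjusted over the list alone, median -0.42, camera adjusted p = 0.0064, adjusted p = 0.166 with an estimated correlation). Scd1 changed by -0.90 ± 0.11. ATF4 and amino acid response genes rose in 11 of 42 cases (12 adjusted over the list alone, median 0.14, camera adjusted p = 0.000978, adjusted p = 0.108 with an estimated correlation), among them Chac1 (1.86 ± 0.18) and the cystine transporter gene Slc7a11 (1.81 ± 0.20). Of 18 unfolded protein response genes, Dnajb9 (1.33 ± 0.14) and Herpud1 (0.85 ± 0.12) rose (2 adjusted over the list alone, median 0.19, camera adjusted p = 0.0104, adjusted p = 0.0924 with an estimated correlation). Toll-like receptor pathway components went both ways, 11 of 37 higher, as Irak2 (1.86 ± 0.17), and 5 lower (the same adjusted over the list alone, median 0.13, camera adjusted p = 0.0196, adjusted p = 0.16 with an estimated correlation). Mitochondrial respiratory chain genes had a median of -0.16 with 4 of 50 lower and 0 adjusted over the list alone (camera adjusted p = 0.0196, adjusted p = 0.252 with an estimated correlation). Without CpG 3 this last list gave an adjusted p of 0.124. Members of other lists changed without a set call: the glucose transporter gene Slc2a1 (1.25 ± 0.11) among glycolysis and hypoxia genes (adjusted p = 0.0517 for the list), Plk2 (2.71 ± 0.16) among p53 targets (0.847) and Hmox1 (1.43 ± 0.26) among NRF2 targets (0.534). Among macrophage identity genes (0.417), Adgre1, the F4/80 gene, rose (1.52 ± 0.20) and Fcgr3 fell (-1.39 ± 0.15).

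The comparison named in the series' design was CpG with gefitinib against CpG alone, and it asks what the inhibitor does to the CpG response. In cells given both, the inflammatory transcripts were far lower than with CpG alone. Il1b was at least 168-fold lower (adjusted p = 1.32e-12), Cxcl2 at least 87.8-fold (adjusted p = 7.43e-14) and Ifnb1 at least 7.46-fold (adjusted p = 2.57e-10), and Tnf changed by -4.36 ± 0.15 (adjusted p = 1.23e-10). Hmgcs1, which encodes the HMG-CoA synthase of cholesterol synthesis, was higher (1.84 ± 0.22, adjusted p = 2.71e-05).

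In this comparison 3019 of the 8101 genes (37.3%) differed, 1786 higher and 1233 lower with gefitinib, and at least 2-fold differences numbered 273 higher and 320 lower. Cyclic loess gave 1546 higher and 1388 lower, and median scaling 1212 and 789. The chemokine genes Ccl7 and Ccl2 were lower. Ccl7 was so at least 64.4-fold (adjusted p = 2.3e-12), and Ccl2, detected on 1 of 3 arrays of CpG with gefitinib, changed by -6.74 ± 0.23. Csf3 was at least 38.1-fold lower by its brighter probe (adjusted p = 1.51e-12), while its other probe did not pass the threshold (-0.20, adjusted p = 0.478), and Phlda1 was at least 32.8-fold lower (adjusted p = 8.96e-12). Saa3 changed by -5.57 ± 0.25, Socs3 by -4.86 ± 0.17, Nfkbiz by -4.81 ± 0.15, and Oasl2, an interferon-stimulated gene detected on 1 of 3 arrays of CpG with gefitinib, by -4.83 ± 0.11. Il6 was at least 6.73-fold lower (adjusted p = 5.59e-11) and Ptgs2 at least 3.57-fold (adjusted p = 2.88e-05). Cxcl10, detected on 1 of 3 arrays of CpG with gefitinib, changed by -4.35 ± 0.21 (adjusted p = 3.06e-09) and Dusp6 by -0.83 ± 0.12 (adjusted p = 0.000108). Cxcr4 was the highest named gene with gefitinib (4.22 ± 0.20, adjusted p = 2.61e-09), with detection on 1 of 3 CpG arrays. St6gal1 was higher by 2.80 ± 0.15, Fndc10 by 2.78 ± 0.13, Asb10, detected on 2 of 3 CpG arrays, by 2.61 ± 0.18, Agap1 by 2.33 ± 0.17 and Cytip by 2.20 ± 0.14. The iron exporter gene Slc40a1 was higher by 2.27 ± 0.12, the metallothionein gene Mt2 by 2.61 ± 0.30, and Mvd, a mevalonate pathway gene, by 2.27 ± 0.23. Ypel3 was higher by its brighter probe (2.96 ± 0.19, adjusted p = 8.56e-08) and not by its other probe (-0.11, adjusted p = 0.708).

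Chemokine genes and other lists of inflammatory genes were lower with gefitinib. All 10 chemokine genes were lower (10 adjusted over the list alone, median -4.03, camera adjusted p = 8.81e-18), including Ccl3 (-4.47 ± 0.16), as were 14 of 17 inflammatory cytokine genes, with 1 higher (the same adjusted over the list alone, median -2.18, or -2.06 with bounds, camera adjusted p = 1.87e-14). Il1a was at least 19.7-fold lower, Il1rn changed by -4.78 ± 0.18, and the cytokine gene that was higher was again Il15 (1.13 ± 0.19). Interferon-stimulated genes were lower in 43 of 45 cases (43 adjusted over the list alone, median -1.98, or -1.94 with bounds, camera adjusted p = 2.13e-40). Usp18 changed by -4.74 ± 0.12 and Isg15 by -4.28 ± 0.16. Among 4 type I interferon genes Ifnb1 alone was lower, and the set test gave an adjusted p of 0.0572. NF-kB regulators and feedback genes were lower in 16 of 24 cases and 1 was higher (the same adjusted over the list alone, median -1.22, camera adjusted p = 3.24e-11). Zc3h12a changed by -3.19 ± 0.18. Macrophage effector genes were lower in 16 of 18 cases (16 adjusted over the list alone, median -1.51, or -1.36 with bounds, camera adjusted p = 1.39e-13). The urokinase receptor gene Plaur changed by -3.71 ± 0.15. ERK-dependent genes were lower in 15 of 25 cases and higher in 2 (the same adjusted over the list alone, median -0.83, camera adjusted p = 7.95e-08). Ier3 changed by -3.11 ± 0.16 and Dusp2 by -2.65 ± 0.12. Of 6 EGF receptor family, ligand and sheddase genes, 4 were lower (4 adjusted over the list alone, median -0.61, camera adjusted p = 0.00659). Errfi1 changed by -1.75 ± 0.11, Rhbdf2 by -1.23 ± 0.10 and the sheddase gene Adam17 by -0.65 ± 0.12. Unfolded protein response genes were lower in 9 of 18 cases (11 adjusted over the list alone, median -0.38, camera adjusted p = 0.000281). The chaperone gene Hspa5 changed by -1.41 ± 0.29. Mitosis genes were higher in 15 of 25 cases (18 adjusted over the list alone, median 0.44, camera adjusted p = 0.00011). Kif11 changed by 0.84 ± 0.13 and Kif2c by 0.85 ± 0.15. Each of these calls held with an estimated correlation.

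Lipid and lysosome genes were higher in cells given both agents than with CpG alone. Cholesterol synthesis and uptake genes were higher in 16 of 20 cases (16 adjusted over the list alone, median 0.95, camera adjusted p = 2.05e-07, adjusted p = 0.12 with an estimated correlation). The sterol carrier gene Stard4 changed by 1.72 ± 0.19. Fatty acid synthesis and LXR target genes were higher in 12 of 16 cases and 1 was lower (the same adjusted over the list alone, median 0.61, camera adjusted p = 0.000288, adjusted p = 0.102 with an estimated correlation). Scd1 changed by 1.80 ± 0.11 and Acss2 by 1.35 ± 0.14. Lysosome and autophagy genes were higher in 18 of 38 cases and 4 were lower (the same adjusted over the list alone, median 0.32, camera adjusted p = 0.00616, adjusted p = 0.13 with an estimated correlation). Gpnmb changed by 1.29 ± 0.14, Psap by 1.23 ± 0.11 and the acid lipase gene Lipa by 1.14 ± 0.12. ATF4 and amino acid response genes were higher in 17 of 42 cases and 2 were lower (the same adjusted over the list alone, median 0.26, camera adjusted p = 0.0141, adjusted p = 0.178 with an estimated correlation). The glycine transporter gene Slc6a9 changed by 2.05 ± 0.25 and Slc1a4 by 1.52 ± 0.16. DNA replication genes were higher in 12 of 33 cases (14 adjusted over the list alone, median 0.28, camera adjusted p = 0.0065, adjusted p = 0.128 with an estimated correlation). E2f2 changed by 1.02 ± 0.27.

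Metabolic, receptor and cell identity lists moved in part. Toll-like receptor pathway components were lower in 13 of 37 cases and 3 were higher (14 and 3 adjusted over the list alone, median -0.26, or -0.25 with bounds, camera adjusted p = 0.00899, adjusted p = 0.12 with an estimated correlation). Irak2 changed by -1.70 ± 0.17. Antigen presentation genes were lower in 5 of 19 cases (5 adjusted over the list alone, median -0.29, or -0.17 with bounds, camera adjusted p = 0.011, adjusted p = 0.11 with an estimated correlation). Nlrc5 changed by -0.92 ± 0.17. Glycolysis and hypoxia genes were lower in 8 of 24 cases and 1 was higher (the same adjusted over the list alone, median -0.09, or -0.08 with bounds, camera adjusted p = 0.0235, adjusted p = 0.111 with an estimated correlation). Slc2a1 changed by -1.26 ± 0.11 and the hexokinase gene Hk2 by -0.95 ± 0.10. Macrophage identity genes were lower in 8 of 16 cases and 3 were higher (10 and 3 adjusted over the list alone, median -0.50, or -0.38 with bounds, camera adjusted p = 0.0398, adjusted p = 0.128 with an estimated correlation), a call lost without CpG 2 or CpG with gefitinib 3 (adjusted p from 0.0238 to 0.0863 over the arrays left out). Adgre1 changed by -1.99 ± 0.20 and Fcgr3 by 1.84 ± 0.15. No set call was made for the remaining lists. NRF2 targets were higher in 7 and lower in 3 of 22 cases (adjusted p = 0.587) and p53 targets higher in 7 and lower in 4 of 17 (0.764), among them Sesn1 (1.93 ± 0.14). Alternative activation genes were higher in 2 of 4 (0.343), and osteoclast genes higher in 2 and lower in 2 of 10 (0.764). Ribosomal protein genes were higher in 4 of 34 cases (0.519) and mitochondrial respiratory chain genes in 10 of 50 (0.0643). Among lymphocyte and granulocyte markers 3 of 26 were measured and S100a8, a calgranulin gene, was lower (-3.55 ± 0.18, 0.278 for the list). Among fibroblast and epithelial markers 1 of 16 was measured, with 0 changes.

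The genes that CpG raised were nearly all lower again in the presence of gefitinib. Of the 268 genes at least 2-fold higher with CpG, 262 (97.8%) were lower in CpG with gefitinib than in CpG alone and 0 were higher. Independent lists of these sizes would share 40.8 genes, and 50 simulations of a CpG response left untouched by gefitinib, with the CpG arrays shared, gave 278 induced genes on average and 0 lower with gefitinib. The median change of the 268 genes was 1.64 with CpG and -1.76 on adding gefitinib (1.58 and -1.72 with bounds). With each CpG array held out in turn from the choice of induced genes and then used alone for the comparison with gefitinib, 257 of 267, 256 of 273 and 258 of 268 genes were lower. A single array has no spread of its own, and the pooled spread of the other arrays was taken to hold for it. The 6 exceptions, named after their values were seen, were the dendritic maturation marker Cd83 (-0.22, adjusted p = 0.216), Chac1 (-0.02, adjusted p = 0.950), Cth (-0.14, adjusted p = 0.515), Rilpl2 (-0.47, adjusted p = 0.0647), Slc7a11 (-0.51, adjusted p = 0.0614) and the angiogenic factor gene Vegfa (-0.00, adjusted p = 0.999). Cd83, Chac1, Slc7a11 and Vegfa also rose with gefitinib alone, as given below. None of the 6 passed the threshold between CpG with gefitinib and gefitinib alone, so no CpG response kept under gefitinib was detected for them. In simulated data 40% of changes of 0.5 log2 units were recovered in that comparison, so a small kept response is not excluded. Of the 118 genes at least 2-fold lower with CpG, such as Cxcr4 and St6gal1, 116 (98.3%) were higher on adding gefitinib and 0 were lower. The 50 simulations, run again for such genes, gave 138 reduced genes on average and at most 1 higher with gefitinib. With each CpG array held out in the same way, 108 of 122, 93 of 119 and 114 of 133 genes were higher.

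Whether cells already given gefitinib still answered CpG was addressed by comparing CpG with gefitinib against gefitinib alone. Tnf was higher by 0.42 (95% interval 0.11 to 0.73), which did not pass the threshold (limma, adjusted p = 0.999938), against 4.17 without gefitinib. Il1b and Cxcl2 were detected in neither group. For Ccl2 the difference was 0.10 (95% interval -0.41 to 0.60) and for the interferon-stimulated gene Isg15 0.10 (95% interval -0.25 to 0.45). By limma 0 of the 8101 genes passed the threshold, and 252 had an unadjusted p under 0.05, where 405.05 would be expected by chance. With the replicate number as a block, 388 genes had such a p, and 665 in a fit on the 6 arrays compared, again with 0 past the threshold by limma. The largest difference of any gene was 0.72 in size, and the smallest adjusted p was 0.999938. Over the 268 CpG-induced genes the median difference was 0.02 (0.0174 to 0.0418 over the arrays left out), or 0 with bounds for the 66 detected on no array of a group. The median width of the 95% interval on either side, for single genes, was 0.323. In simulated data 40% of changes of 0.5 log2 units were recovered in this comparison, so small responses of single genes could be missed. Over the 386 genes that CpG changed at least 2-fold, the slope of the response with gefitinib on that without was 1.83%. In 27 lists 0 genes passed the threshold. Fatty acid synthesis and LXR targets (median -0.12) and lysosome and autophagy genes (median -0.11) each had a camera adjusted p of 0.000639, and an adjusted p = 0.363 with an estimated correlation. Without gefitinib 3 the lysosome list had an adjusted p of 0.0686. Interferon-stimulated genes had a median of -0.01 (camera adjusted p = 0.604).

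**Figure D2:**
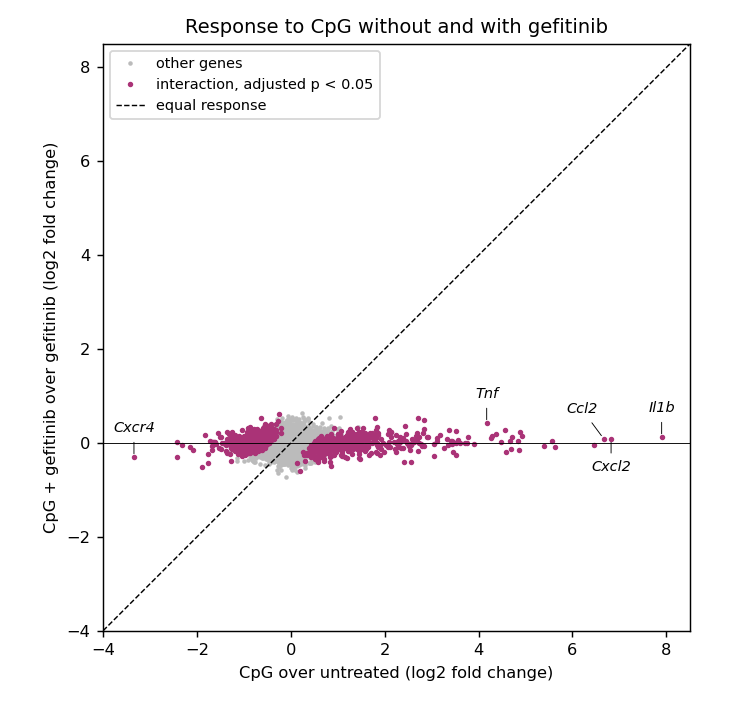
Fitted log2 change of each tested gene with CpG over untreated (horizontal axis) against that with CpG and gefitinib over gefitinib (vertical axis), with the 1000 genes whose interaction passed the threshold in purple and the dashed line marking equal responses. The 8101 points lie along the horizontal line at 0, with no vertical change over 0.72 in size. Genes not detected in a group are drawn at their fitted values.

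The difference between these responses was tested as an interaction, which 1000 genes passed, 514 with a higher and 486 with a lower response in the presence of gefitinib. Their balance depended on the scaling, with 410 higher and 555 lower under cyclic loess and 253 and 281 under median scaling. Tnf had an interaction of -3.75 ± 0.21 (adjusted p = 4.18e-08) and Saa3 of -5.52. Il1b, Cxcl2, Il6, Ifnb1 and Ccl7, detected in no group but CpG alone, passed too, as did Cxcl10, detected on no gefitinib array (adjusted p = 4.66e-07), and none of these has an exact size. Dusp6 passed with -0.79 ± 0.17 (adjusted p = 0.00689), and lost its call when arrays were scaled to a common median. Upward interactions were led by genes that CpG lowered without gefitinib, such as Cxcr4 (3.04 ± 0.28), Asb10 (2.44 ± 0.25), Cytip (2.28), St6gal1 (2.13) and the histone gene H2ac11 (2.00 ± 0.34). Of the 268 CpG-induced genes 263 had a lower response with gefitinib. This count and the leading upward genes follow largely from the size of the CpG response. No gene differed by over 0.72 between CpG with gefitinib and gefitinib alone. The interaction also subtracts the change by which the 268 genes were chosen, and no array was held out for this count. Interferon-stimulated genes had an interaction in 41 of 45 cases, all lower (median -1.74, camera adjusted p = 3.26e-58). DNA replication genes had one in 17 of 33, all higher (median 0.68, camera adjusted p = 1.82e-11). Both calls held with an estimated correlation. They largely restate the CpG response of these lists without gefitinib (medians 1.77 and -0.54), which the interaction subtracts. Cholesterol synthesis genes had 0 interactions by limma (camera adjusted p = 0.392).

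Gefitinib alone changed genes of amino acid and sterol metabolism. Among the genes that rose were Slc6a9, a glycine transporter gene (2.01 ± 0.25, adjusted p = 0.000869), the folate enzyme gene Aldh1l2 (2.08 ± 0.18, adjusted p = 0.000146) and Hmgcs1 of the mevalonate pathway (1.49 ± 0.22, adjusted p = 0.00271). Tnf changed by -0.61 ± 0.15 (adjusted p = 0.0229), a call lost without any 1 of the 6 arrays compared (adjusted p up to 0.0819 over the arrays left out), and with cyclic loess or median scaling (adjusted p from 0.0047 to 0.0674 over the alternatives). Il1b, Il6, Ifnb1 and Ptgs2 were detected in neither group, and Cxcl10 on 1 of 3 untreated and 0 gefitinib arrays, so that no change of it can be given. Dusp6 did not pass the threshold (-0.04 ± 0.12, adjusted p = 0.876).

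Against untreated cells 632 of the 8101 genes (7.80%) changed with gefitinib, 402 upward and 230 downward, and at least 2-fold changes numbered 33 upward and 6 downward. The count moved with the processing, to 137 (87 upward and 50 downward) with median scaling and 956 without background correction. It moved with single arrays as well: it was 345, 321 and 366 without untreated 1, 2 and 3, and 374, 354 and 206 without gefitinib 1, 2 and 3. The neutral amino acid transporter gene Slc1a4, detected on 1 of 3 untreated arrays, rose by 1.75 ± 0.16, and the stress genes Chac1 and Slc7a11 by 1.63 ± 0.18 and 1.49 ± 0.20. Mt2 rose by 1.94 ± 0.30, Mvd by 1.49 ± 0.23 and Aacs, an acetoacetate-activating enzyme gene, by 1.43 ± 0.19. Ypel3 rose by its brighter probe (1.44 ± 0.19) and not by the other (0.22, adjusted p = 0.564). Among genes that fell, the zinc transporter gene Slc39a10, detected on 1 of 3 gefitinib arrays, changed by -1.37 ± 0.19 and the lymphotoxin gene Ltb by -1.22 ± 0.23. The VEGF receptor gene Flt1 changed by -1.19 ± 0.15, Gpr84 by -1.16 ± 0.21, the leukotriene enzyme gene Alox5 by -0.96 ± 0.11 and Fos by -0.93 ± 0.17. Among these genes with the largest changes, calls lost without some single array included those of Fcgr1 (-1.04 ± 0.21, adjusted p = 0.011, and 0.0566 without gefitinib 3), Id1 (-1.13 ± 0.29, adjusted p = 0.0312, up to 0.128 over the arrays left out), Cacybp (-0.97 ± 0.25, adjusted p = 0.0326, up to 0.125) and Nono (lower with adjusted p = 0.0465, up to 0.183). Id1 was detected on 2 of 3 gefitinib arrays.

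As fixed lists, amino acid response and sterol genes were among those that rose with gefitinib alone. ATF4 and amino acid response genes rose in 22 of 42 cases (28 adjusted over the list alone, median 0.48, camera adjusted p = 5.51e-17), a call that held with an estimated correlation. Cholesterol synthesis and uptake genes rose in 13 of 20 cases (14 adjusted over the list alone, median 0.91, camera adjusted p = 9.45e-14, adjusted p = 0.0789 with an estimated correlation), including Cyp51 (1.28 ± 0.21) and Nsdhl (1.13 ± 0.12). Fatty acid synthesis and LXR target genes rose in 9 of 16 cases (10 higher and 1 lower adjusted over the list alone, median 0.49, camera adjusted p = 2.45e-07, adjusted p = 0.0539 with an estimated correlation), including Scd1 (0.91 ± 0.11). Lysosome and autophagy genes rose in 7 of 38 cases (21 adjusted over the list alone, median 0.31, camera adjusted p = 1.62e-07, adjusted p = 0.0539 with an estimated correlation), including Psap (0.71 ± 0.11, adjusted p = 0.0037, between 0.0001 and 0.15 over the alternatives, the highest with median scaling). DNA replication genes fell in 6 of 33 cases (15 adjusted over the list alone, median -0.30, camera adjusted p = 7.35e-10), including the origin licensing gene Cdc6 (-0.74 ± 0.11), a call that held with an estimated correlation. Interferon-stimulated genes went both ways, 2 of 45 higher and 4 lower (3 and 4 adjusted over the list alone, median -0.03, camera adjusted p = 0.297). Ifi47 changed by -0.84 ± 0.15. No set call was made for inflammatory cytokines (0.77), chemokines (0.427), NF-kB regulators (0.95), macrophage effector genes (0.631) or the EGF receptor family (0.829). Single members did change there, as Cd83 (1.23 ± 0.13), Vegfa (0.90 ± 0.12), Plaur (-0.92 ± 0.15) and the chemokine gene Ccl9 (-0.74 ± 0.11). Egr2, of the ERK-dependent and alternative activation lists, which had no set call either, was at least 2.22-fold higher (adjusted p = 0.00505).

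**Figure D3:**
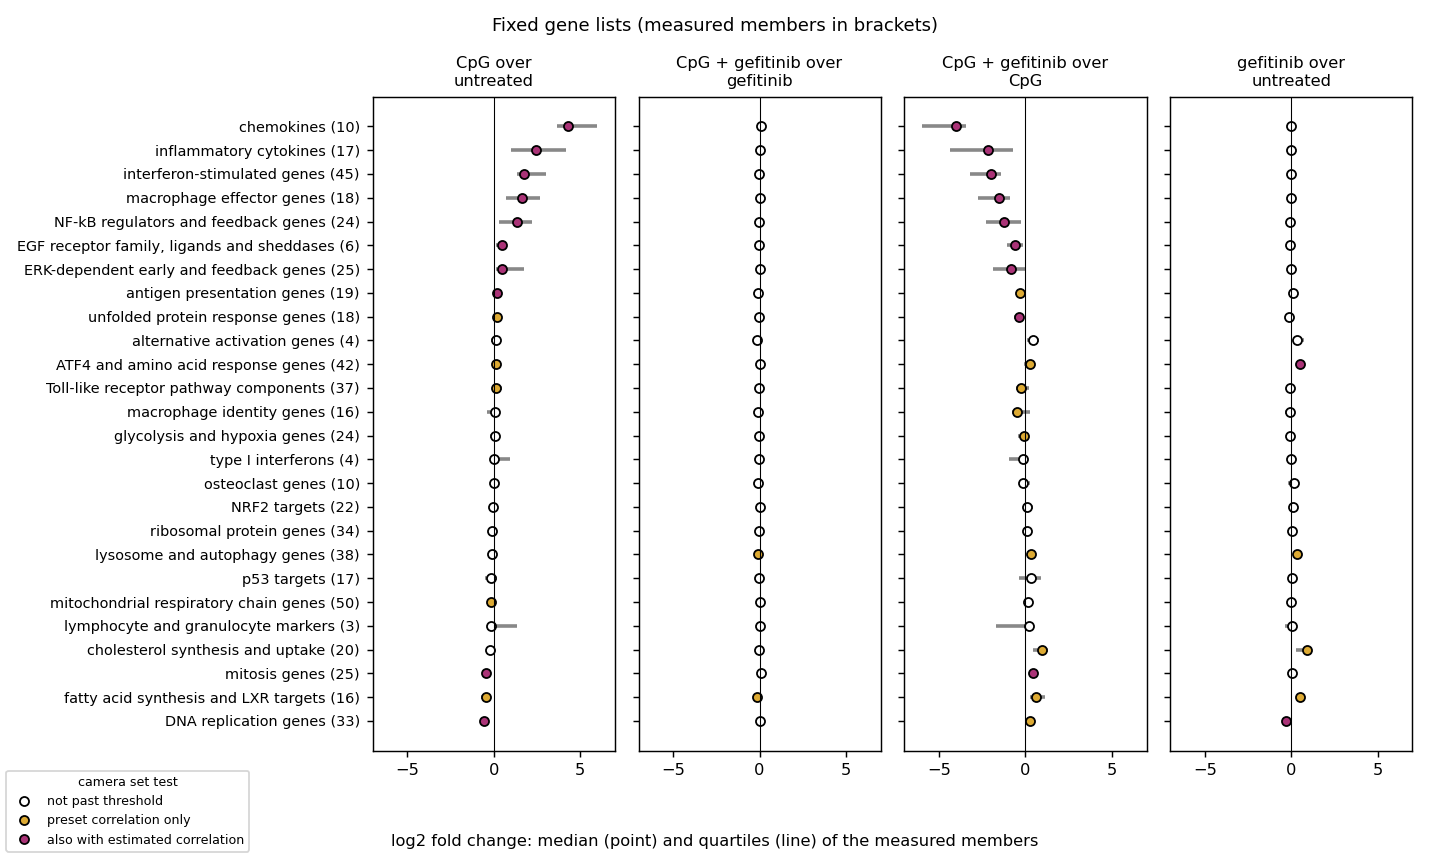
Median (point) and quartiles (line) of the log2 change of the measured members of each fixed list with at least 3 of them, in 4 comparisons, with the camera call shown by the fill. Chemokines have a median of 4.32 with CpG and -4.03 on adding gefitinib, and the cholesterol list a median of 0.91 with gefitinib alone.

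The effects of gefitinib in cells without and with CpG came from comparisons that share no array. The latter also holds the CpG response, which was not detected in the arrays of CpG with gefitinib, for a reason that stays open. Of the 402 genes higher with gefitinib alone, such as Slc6a9, Hmgcs1 and Mvd, 318 (79.1%) were also higher in CpG with gefitinib than in CpG and 9 were lower. Independent lists would share 88.6 (two-sided Fisher's exact test across genes, p = 2.51e-139). Genes are not independent units, and both comparisons use the same estimate of each gene's spread. Such p-values, here and below, therefore do not measure how well an effect of gefitinib repeats. Of the 318 genes, 153 were lowered by CpG alone, so that a CpG response absent for whatever reason would move them the same way. The other 165 did not pass the threshold with CpG. Of the 230 lower with gefitinib alone, such as Alox5 and Flt1, 139 (60.4%) were also lower in the presence of CpG, 9 were higher, and independent lists would share 35.0 (Fisher's exact test, p = 2.03e-57). Of these 139, CpG alone raised 54, and 85 did not pass the threshold with it. An interaction passed the threshold for 83 of the 402 and 69 of the 230 genes.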

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

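Among the tests below, those of RNA from cells given gefitinib alone and of fewer cells in DNA replication, and the splits of the arrays of CpG with gefitinib and gefitinib alone, were chosen after the result was seen, as were the values by replicate number and the histone H2A genes themselves.

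Inflammatory genes stood out because their response to CpG differed between cells without and with gefitinib, by the interaction test that 1000 genes passed. The response with gefitinib minus that without was, in log2 units as fitted, -7.78 for Il1b, -6.73 for Cxcl2, -6.57 for Ccl2, -6.48 for Ccl7, -5.72 for Csf3, -5.52 for Saa3, -5.45 for Phlda1, -5.00 for Nfkbiz, -4.83 for Socs3 and -4.79 for Il1a. Fitted values of genes not detected in some group, such as Il1b, Cxcl2 and Klhl30, are no bound. In the other direction it was 3.04 for Cxcr4, 2.44 for Asb10, 2.28 for Cytip, 2.13 for St6gal1, 2.06 for Fndc10, 2.00 for H2ac11, 1.93 for Agap1, 1.77 for Klhl30, 1.76 for H2ac21 and 1.70 for H2ac15. Of 100 splits that moved the gefitinib labels among the 6 arrays with CpG and among the 6 without, 7 gave at least 1000 genes, the real split included, and the highest other gave 1737, so this test does not exclude chance. All 7 parted the arrays with CpG as labelled, as 9 of the drawn splits did, and the splits that regrouped those arrays gave at most 1 gene, which points to the difference between CpG and CpG with gefitinib as the structure behind the count.

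For each comparison of 3 against 3 arrays the 10 splits are too few for a share under 0.05. For CpG with gefitinib against CpG, CpG against untreated, and gefitinib against untreated, the real splits gave 3019, 2054 and 632 genes and the highest other split 0 in each case, so that 1 of 10 splits gave as many. For CpG with gefitinib against gefitinib all 10 splits gave 0 genes by limma.

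In cells given gefitinib neither Tnf nor Isg15 nor any other gene showed a CpG response past the threshold, 0 genes by limma with 252 at an unadjusted p under 0.05 (388 with the replicate block). Scaling and background correction are argued against as the reason. Over 6 of them the median response of the CpG-induced genes was at most 1.91% of that without gefitinib. Too few arrays are argued against only for responses of at least 0.5 times those without gefitinib. Of the CpG-induced genes, 96.3% had an upper 95% limit below 0.5 times their change without gefitinib. However, 66 of the 268 were detected on no array of a compared group, so that a response below detection would be missed. Smaller responses are left open. Arrays that hold RNA of cells given gefitinib and no CpG cannot be told apart from a blocked response, because the median change of 0.0203 (up to 0.0418 with single arrays left out) lies within those of the other splits (up to 0.0556, or 0.0220 among the 4 that part all same-numbered pairs). Tnf was higher in each such pair (by 0.67, 0.20 and 0.39). With a block on these 6 arrays 665 genes had an unadjusted p under 0.05 by limma, against at most 371 in the other 3 of the 4 splits. Of the CpG-induced genes 52 were above 0 and 38 below 0 in all 3 pairs. The other splits, whose sign is arbitrary, gave 28 and 23, 25 and 43, and 36 and 22. No gene passed the threshold, and 4 splits are too few to settle it. A block of the CpG response by gefitinib, which the design sets out to examine, may be the reason and stays open.

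Histone H2A genes were lower with CpG, 9 of 11 past the threshold with a median of -1.52, and 10 of 11 were higher on adding gefitinib (median 1.87). Probes that cannot tell the near-identical copies apart may count a single change several times, and cannot be told apart from a shared change: the deviations from group means correlated with a mean pairwise r of 0.638 across the 12 arrays (0.837 among the 9 lower genes, at most 0.252 in 1000 random sets). A smaller share of cells in DNA replication could lower them too, and with gefitinib alone the DNA replication genes fell (median -0.30) while 0 of the H2A genes passed the threshold (median 0.236). That value lies within the other splits (up to 0.514), so this test leaves it open. The median with CpG was below 0 under each of 6 scalings.

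Probes without a gene name lie outside the gene tests, and 223 of 694 passed the threshold in CpG with gefitinib against CpG and 162 in CpG against untreated. Their genes were not identified, and no explanation was tested.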

How the results depend on the processing

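All alternatives below but the replicate block on 6 arrays were planned. A 2-fold minimum or an adjusted p under 0.01 gives fewer genes by construction, and no fold minimum gives more induced genes, while elsewhere the cause was not tested. For CpG with gefitinib against CpG (3019 genes) median scaling gave 2001, a 2-fold minimum 593 and an adjusted p under 0.01 1967 genes. For CpG against untreated (2054) the last 2 gave 386 and 1244. For gefitinib against untreated (632) no background correction gave 956, the deposited values 955, median scaling 137, a 2-fold minimum 39 and an adjusted p under 0.01 164. For the interaction (1000) median scaling gave 534, a 2-fold minimum 375 and an adjusted p under 0.01 519. CpG-induced genes lower with gefitinib (262 of 268) numbered 155 of 156 without background correction, 157 of 158 with the deposited values, 159 of 162 with detection p under 0.01 on all arrays and 708 of 813 with no fold minimum. Lists past the threshold numbered 9 with an estimated correlation for CpG with gefitinib against CpG (18), and for gefitinib against untreated (5) 8 with median scaling, 2 with an estimated correlation and 9 with fry. For CpG with gefitinib against gefitinib (2) they numbered 4 with median scaling, 4 with the mean of probes, 0 with an estimated correlation and 0 with fry, and for the interaction (16) 10 with an estimated correlation. The set call for macrophage identity genes in CpG with gefitinib against CpG was lost under 5 settings besides the estimated correlation and without CpG 2 or CpG with gefitinib 3. Medians reversed for type I interferons in the interaction with strict detection (0.094) and for glycolysis and hypoxia genes in the interaction with median scaling (0.0167). Leaving out single arrays gave 2450 to 3064, 1642 to 1991, 206 (without gefitinib 3) to 856 (without CpG 2), 0 to 0 and 770 to 1017 genes for CpG with gefitinib against CpG, CpG against untreated, gefitinib against untreated, CpG with gefitinib against gefitinib and the interaction, 259 to 269 CpG-induced genes lower with gefitinib, a median change of the CpG-induced genes in CpG with gefitinib against gefitinib of 0.0174 to 0.0418 (without CpG with gefitinib 2, against 0.0203), and, in the same order, 18 to 19, 14 to 16, 5 to 7, 1 (without gefitinib 3) to 4 (without gefitinib 2) and 14 to 16 lists. Named genes kept direction and side of the threshold in 5560 values with an array left out and 5268 under other settings, lost the call in 206 and 110, gained it in 42 and 143, and reversed in 0. The replicate number as a replicate block gave 3309, 2314, 942, 0 and 1183 genes in that order. Chosen after the results were seen, a replicate block on the 6 arrays compared gave 0 genes for CpG with gefitinib against gefitinib, with 665 at an unadjusted p under 0.05 by limma. Over all groups, 11 of 18 same-numbered pairs had deviations correlated over 0.1 (-0.15 to 0.35). The mean r was 0.142 for same-numbered pairs and -0.071 for other pairs, and 10 of 12 arrays correlated best with their own number. Deviations thus went in part with the replicate number, which the main fit does not take into account. All 3 such pairs of CpG with gefitinib and gefitinib (0.237 to 0.277), and of CpG with gefitinib and CpG (0.110 to 0.350), were over 0.1. A block for the slide was not run because the files give no slide, and list tests were not run with array weights. Signal over background limits the genes detected in a single group, whose folds are bounds.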

Other observations

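The test of untreated arrays low by chance, for the cholesterol genes, was chosen after the result was seen, as was leaving out single arrays for the CpG-induced genes.

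Of the 268 CpG-induced genes, 26 (9.70%) fell with gefitinib in the absence of CpG, among them Ltb, Gpr84, Plaur, Ccl9 and Fos, and 8 rose, while 204 of the 7833 other genes fell (2.60%; two-sided Fisher's exact test across genes, p = 3.39e-08; odds ratio 4.02, 95% interval 2.51 to 6.20). With single arrays left out, between 13 (without untreated 1 or gefitinib 3) and 29 (without CpG 2) of the induced genes were lower, with odds ratios from 2.84 to 8.09. Untreated arrays are shared by both comparisons, and in 50 simulations with a CpG response and no effect of gefitinib this raised the median change with gefitinib by 0.012, away from the pattern. Genes are not independent replicates, and the median of all 268 was -0.05. Of the 118 genes that CpG lowered at least 2-fold, 8 fell with gefitinib alone (6.78%, with 3.35 expected of independent lists). A further 17 rose (14.4%, with 5.86 expected), so genes that CpG lowered were called more often too. A lower basal activity of part of the CpG-responsive genes under gefitinib remains a hypothesis. The share above restates the observation in the same data and is no separate test of it.

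Cholesterol synthesis genes were higher with gefitinib alone (median 0.91). Untreated arrays that happened to be low are argued against, since the median was 0.952 in CpG with gefitinib against CpG, which shares no array with the former comparison. Scaling or background correction is argued against by a lowest median of 0.606 over 6 of them, and a single array by a lowest median of 0.726 with each left out. An effect of gefitinib on sterol synthesis may underlie the pattern, as a hypothesis. The list's set call was lost with an estimated correlation (adjusted p = 0.0789).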
